A study of Mus musculus with 8 samples.

How the data were processed

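The values are gene counts as deposited by the authors, in 1 file per library, and they were made from RNA-seq reads aligned to GRCm38 (mm10). Per the labels' protocols, total RNA was extracted with the RNeasy Plus Micro Kit, libraries were made with a stranded total RNA kit for low input (SMARTer Pico, version 2) and read in pairs on a NextSeq 550. Per the submitters' processing notes, STAR 2.5.0a and HTSeq 0.6.1 were used. Per the file headers, the 3T3 counts came from merged alignment files with 72 hours in their names, doxycycline in those of the induced libraries alone and Cas9 in all, in a layout that is not HTSeq's own. The program that counted the 3T3 reads, the annotation release, the strand setting, the alignment filters and the handling of duplicates are not given in the sources used here. The 3T3 files hold 53465 Ensembl genes and those of Scid.adh hold 31053 genes, of which 30731 are in both. Symbols, positions and exon overlaps came from GENCODE M21, in which 105 and 42 of these genes were not found.

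Rows that summarise unassigned reads, present in the Scid.adh files only, were left out. Of all reads in these files, summary rows included, reads outside any gene were 21.3% and 21.6% with the empty vector and 22.3% and 25.8% in the knockout, and ambiguous reads 2.28%, 2.31%, 2.44% and 2.20%. Genes were filtered with edgeR's filterByExpr, scaled by TMM and tested per line with edgeR's robust quasi-likelihood F-test with Benjamini-Hochberg adjustment (edgeR 4.0.16 in R 4.3.3), with a call at an adjusted p under 0.05. The biological coefficient of variation was 2.41% in 3T3 and 5.94% in Scid.adh, where the file labels do not tell separate cultures from repeated libraries. Adjusted p-values of single genes come from this test. Values of genes are CPM, mean and SD over 2 libraries, and log2 fold changes are induced minus normal, and knockout minus empty vector.

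The 21 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members. Adjusted p-values of lists come from this test, beside a run with an estimated correlation and fry. The lists were T cell receptor signalling and surface, DN2 and DN3 thymocyte, T lineage transcription factors, early progenitor factors, Notch targets, Wnt targets, NK and innate lymphoid, B lineage, myeloid, fibroblast matrix, contractile and YAP targets, cell cycle, interferon-stimulated, p53 targets, immediate early, integrated stress response, glycolysis and hypoxia, cholesterol synthesis, cohesin and CTCF, mitochondrial transcripts and T cell receptor loci. Lists were also ranked among 10000 random gene sets drawn with the same spread over 10 classes of mean CPM, a step added after the data were seen. The difference between lines was tested with the same edgeR method on the 15854 genes tested in a joint fit, and shared calls with Fisher's exact test. The share of called genes whose next tested gene was called in the same direction was compared with 10000 random placements of the calls, and chromosome medians with 10000 random gene sets for chromosomes with at least 20 tested genes.

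Genes were named by a rule fixed before the data were examined. It took Tcf7 and Lef1, and per line the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups, passing over unnamed gene models. It also took up to 2 called members per list (up to 4 in the T cell receptor, DN2 and DN3, and T lineage factor lists), or the most abundant member where none passed, and the 4 most firmly shared genes per direction class. A gene at 0 in a group was given as a bound from 3 counts over that group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval.

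Alternatives fixed in advance were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 1 CPM, the replicate number as a block, each library left out in turn, a joint fit of 8 libraries and a test against 1.5-fold. Corrections of log2 CPM against expression level or GC content by loess, a minimum of 5 CPM in the gene tests, and 2 more settings of the neighbour test were added after the data were seen. The alternative for values that are not counts did not apply. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

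The steps were tested on simulated data with the dispersion of each line. Changes of 1.25-fold, 1.5-fold, 2-fold and 4-fold were planted. The gene test found 34.0%, 54%, 78.7% and 97.9% of them in 3T3, with 3 false calls in a run of 17786 tested genes. In Scid.adh it found 22.4%, 66.7%, 79.2% and 95.8%, with 14 false calls in a run of 11528. Both totals include the planted genes. The list test called 0 of 18 lists without planted change and called a raised list. Simulated genes were drawn independently, so this does not show how the list test behaves when members of a list are correlated. The neighbour test gave p = 0.406 (permutation test) in 3T3 and p = 0.542 (permutation test) in Scid.adh on shuffled calls, and p = 0.001 (permutation test) in both with 200 planted pairs.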

Results

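The series asked how TCF-1 reshapes the folding of the genome in T cells, and the libraries analysed here measured transcript levels in mouse cell lines that gained or lost it. TCF-1 is an HMG-box DNA-binding protein encoded by Tcf7 and is needed for early T cell development in the thymus. The 8 RNA-seq libraries fell into 4 groups with 2 libraries each. NIH-3T3, an embryonic fibroblast line outside the blood lineages, was grown either as normal cells or with TCF-1 induced. Scid.adh, a line from a thymic lymphoma used as a model of DN3 thymocytes, carried either an empty vector or a Tcf7 knockout. DN3 is the double-negative stage 3, by which precursors have committed to the T lineage. Total counts over genes were 16174002 and 17523677 in normal 3T3 cells, 16857868 and 13850213 in induced cells, 10392402 and 9847239 in empty-vector Scid.adh cells and 7740198 and 8217933 in knockout cells. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. CPM are per library size adjusted by TMM (a scaling between libraries), and no molecular identifiers mark copies of the same fragment, so intervals and floors on counts cover counting error only.

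Tcf7 lies on the minus strand of chromosome 11, from 52252371 to 52283014 of GRCm38. It stood at 14.45 and 14.65 CPM (read counts scaled to library size) in the normal 3T3 libraries and at 945.9 and 971.5 CPM in the induced ones, a rise of 6.04 on the log2 scale (SE 0.05, adjusted p = 1.2e-51). In Scid.adh it stood at 1318 and 1325 CPM with the empty vector and at 646.4 and 624.5 CPM in the knockout libraries. This fall of 2.08-fold (log2 fold change -1.06, SE 0.06, adjusted p = 5.06e-08) left Tcf7 transcripts in both knockout libraries, and counts per gene do not show whether those transcripts encode a full protein. The induced fibroblasts held Tcf7 at a level between those of the knockout and the empty-vector T-lineage cells, although the 2 lines were counted on different gene tables. Lef1, the gene of the related HMG-box factor LEF-1 on chromosome 3 (131110471 to 131224356, plus strand), fell in induced 3T3 cells from 11.6 ± 1.76 to 8.91 ± 1.27 CPM (mean ± SD, n = 2 libraries; log2 fold change -0.39, SE 0.13, edgeR adjusted p = 0.0123). That call was lost in DESeq2 and without normal library 1 (log2 fold change -0.23) or induced library 1 (-0.24). In Scid.adh, Lef1 did not pass the test, at 485 ± 4.87 CPM with the empty vector and 467 ± 22.7 CPM in the knockout (log2 fold change -0.05, SE 0.06, edgeR adjusted p = 0.536). It passed downward without knockout library 2 (log2 fold change -0.10) and turned upward with upper-quartile factors (0.03) and after a correction against expression level (0.09).

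**Figure D1:**
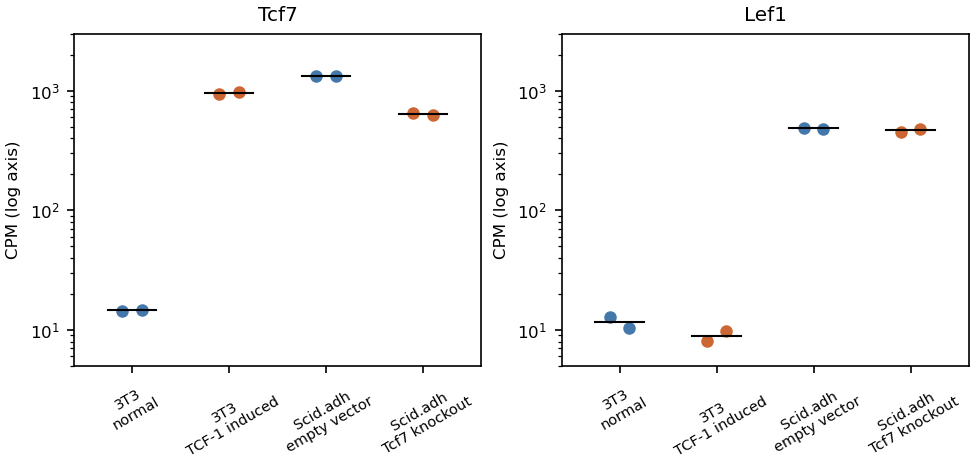
CPM of Tcf7 (left) and Lef1 (right) in each library on a log axis, by group; each point is a library and each bar the mean of its group. Tcf7 rose from 14.45 and 14.65 CPM to 945.9 and 971.5 CPM in induced 3T3 cells and fell from 1318 and 1325 CPM to 646.4 and 624.5 CPM in knockout Scid.adh cells.

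The comparison of induced with normal fibroblasts asks what TCF-1 does in a cell type outside the blood lineages. Among named genes with a mean of at least 5 CPM, the 6 largest rises were those of Tcf7 and the genes that follow. Lcn2 (lipocalin 2, an iron-siderophore binding protein; chromosome 2, 32384633 to 32388252) went from 2.75 ± 0.886 to 213 ± 0.501 CPM (mean ± SD, n = 2), a log2 fold change of 6.28 (SE 0.09). Chil1, a chitinase-like secreted protein, rose by 5.69 (SE 0.15) and Lbp, the lipopolysaccharide-binding protein, by 5.23 (SE 0.16). Oas2, whose enzyme answers viral double-stranded RNA by making a short RNA messenger (chromosome 5, 120730333 to 120749853), rose 64.2-fold (SE 0.23 on the log2 scale) and Ifi44, an interferon-induced gene, by 4.30 (SE 0.17). The deepest falls on the log2 scale were those of Tes, a focal adhesion protein (-2.39, SE 0.07; 99.98 to 19.1 CPM), the flippase gene Atp10d (-2.24, SE 0.14) and the adhesion gene Opcml (-2.11, SE 0.11). They were followed by Postn, which encodes the matrix protein periostin (-2.08, SE 0.04; 791 to 187 CPM), Pappa2, a protease of insulin-like growth factor binding proteins (-2.05, SE 0.12), and the semaphorin receptor gene Plxna4 (-1.99, SE 0.11). The largest adjusted p among these 11 genes, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 4.56e-18. In all, 3361 of 18185 tested genes rose and 3332 fell. DESeq2 called 1803 and 1845, and 480 and 437 genes passed a test against a change of 1.5-fold. Camera called 5 of 18 lists with at least 5 tested members, and 0 of 18 with an estimated correlation between genes. That run also works with the few degrees of freedom that 2 libraries per group leave. The cholesterol synthesis list had an estimated correlation of -0.03, below the preset 0.01. Its unadjusted camera p still went from 5.10e-09 to 0.0241. The lost calls therefore do not show that correlation between genes explains the list changes. Fry, which asks whether the genes of a list move on balance in the same direction and does not compare them with other genes, called 13 of 18. That count depends on the setting: fry called 8 under the replicate block, and 0, 3, 6 and 5 without normal library 1, normal library 2, induced library 1 and induced library 2.

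**Figure D2:**
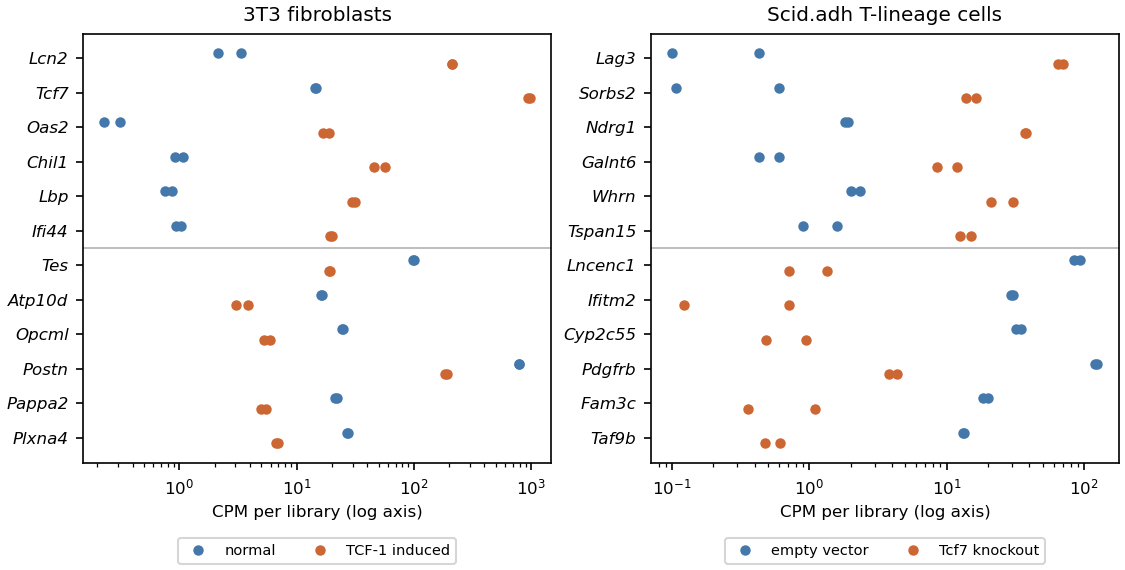
CPM per library, on a log axis, of the 6 genes with the largest rise (above the line) and the 6 with the largest fall (below it) in 3T3 (left) and Scid.adh (right), picked by a rule set before the values were seen. Each point is a library; no point of a control group overlaps the treated group of the same gene, as the rule required.

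Interferon-stimulated genes rose together in the induced fibroblasts: 25 of 27 measured members rose, Ifit2 fell and Oasl1 did not pass, with the same counts when adjusted over the list alone. Their median log2 fold change was 1.97. Ifi44 belongs to this list (0.986 ± 0.0676 to 19.6 ± 0.510 CPM). Where members of a list are named here and below to fill a count, without values, they were chosen after their values were seen. Oas1a, a relative of Oas2, had 0 counts in both normal libraries and 64 in the induced ones, at least 23.4-fold higher against a floor of 3 counts over the normal group. The list's adjusted p from camera was 8.96e-17 (adjusted p = 0.217 with an estimated correlation, the highest of 8 alternatives, whose lowest was 1.26e-17), and the list's median is 1.97 also with Oas1a at its bound. Doxycycline appears in the file headers of the induced libraries and not in those of the normal ones.

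Metabolic and stress genes fell in the same cells. All 20 measured gene entries of the glycolysis and hypoxia list fell (19 symbols, with Aldoa listed under 2 gene identifiers), with a median of -0.39, and the same number fell when adjusted over the list alone. Hk2, the hexokinase that starts glucose breakdown, dropped from 589 ± 3.03 to 151 ± 3.54 CPM (log2 fold change -1.96, SE 0.04) and Ankrd37, a hypoxia-induced gene, fell from 40.9 ± 1.66 to 13.7 ± 0.989 CPM (-1.58, SE 0.08). The list's adjusted p was 5.39e-10 (adjusted p = 0.326 with an estimated correlation, the highest of 8 alternatives, whose lowest was 5.12e-10). All 18 cholesterol synthesis genes fell over all genes and adjusted over the list alone, with a median of -0.49, among them Insig1, the sterol sensor of the endoplasmic reticulum (-0.88, SE 0.05), and the isoprenoid enzyme gene Idi1 (-0.79, SE 0.14). Their adjusted p was 3.06e-08 (adjusted p = 0.217 with an estimated correlation, against a lowest of 2.99e-08). Of 17 immediate early genes, which respond within minutes to growth factors, 13 fell (14 adjusted over the list alone) and Klf4 and Egr2 rose. Fosb, an AP-1 subunit, fell by 1.51 on the log2 scale (243 ± 3.46 to 85.1 ± 2.74 CPM) and Ier3 by 1.11, and the list's adjusted p was 9.24e-05 (adjusted p = 0.334 with an estimated correlation, against a lowest of 3.98e-05). Of 14 measured members of the integrated stress response, 10 fell and Asns rose, over all genes and adjusted over the list alone. Vldlr, a lipoprotein receptor, showed a log2 fold change of -1.13 and Aldh1l2, a mitochondrial folate enzyme, of -1.10, and the list's adjusted p was 0.00103 (adjusted p = 0.326 with an estimated correlation, against a lowest of 0.00102).

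T-lineage lists did not pass camera in the fibroblasts. The medians of T lineage transcription factors (at 98.6%) and Notch targets (at 98.8%) still lay high among random sets matched on level. Fry called T lineage transcription factors (adjusted p = 0.00109, its lowest in 3T3, with the induced gene Tcf7 a member), Notch targets (0.00376) and DN2 and DN3 genes (0.0181). Under the replicate block fry kept the first (adjusted p = 0.0115) but not Notch targets (0.0746) or DN2 and DN3 genes (0.136). Of 30 genes of T cell receptor signalling and the T cell surface, 7 were tested and Cd5, an inhibitory co-receptor, passed over all genes (0.696 ± 0.254 to 1.33 ± 0.453 CPM; log2 fold change 0.97, SE 0.38), while 0 passed adjusted over the list alone. Cd5 was lost in DESeq2, without any filter on low counts, in the fit of all 8 libraries, after a correction against GC content (0.88) and without normal library 2 (log2 fold change 0.63) or induced library 1 (0.55). The list's median (0.02) and mean (0.08) lay above 0 while the test pointed down (adjusted p = 0.951), and it pointed up without normal library 1 (median -0.04). Means of lists, and medians with a library left out, are on the log2 CPM scale of the list test. Of 7 tested DN2 and DN3 genes, Hes1, a Notch-induced repressor, rose from 25.1 ± 1.16 to 49.5 ± 2.97 CPM (log2 fold change 0.97, SE 0.07) and Trib2, a pseudokinase, by 0.53 (SE 0.06). Adjusted over the list alone, 3 rose. That list's median was -0.01, with a mean of 0.23 and a test pointing up (adjusted p = 0.257). Of 23 T lineage transcription factors tested, 6 rose, the induced gene Tcf7 itself among them, and 5 fell (8 and 5 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.257). Notch1, the receptor that drives T cell commitment, rose by 0.96 (SE 0.11), Id2, an inhibitor of E proteins, fell by 1.16 on the log2 scale, and Ets2 fell by 0.48, beside Bcl6, Ets1 and Lef1. Gata3, a T cell master regulator, did not pass, at 1.44 ± 0.0868 and 2.23 ± 0.0952 CPM (log2 fold change 0.63, SE 0.27, adjusted p = 0.0641), but passed after a correction against GC content (0.63). Gata3, and below Rad21 and Ctcf, were added to the named genes after their values were seen. Of 12 Notch targets, Hes1, Trib2, Notch1 and Igf1r rose and Myc fell (6 up and 1 down adjusted over the list alone; adjusted p = 0.243).

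Lists of other lineages and processes had no camera call in 3T3 when all 4 libraries were used. Fry called the NK and innate lymphoid (adjusted p = 0.0020), contractile and YAP (0.00918), myeloid (0.0127), Wnt (0.0143) and p53 (0.0382) lists. It did not call those of fibroblast matrix, cell cycle or early progenitors. Of 30 fibroblast matrix genes, 25 changed, in both directions (13 up and 12 down, or 14 and 12 adjusted over the list alone). Col4a1, a basement membrane collagen, rose by 1.86 (SE 0.03; 454 ± 10.6 to 1644 ± 46.8 CPM) against the fall of Postn. The median of that list was -0.05 and its mean -0.03, while the test pointed up (adjusted p = 0.965), and down without normal library 2 (median -0.04). Of 16 contractile and YAP target genes, 4 rose (Acta2, Axl, Myl9 and Lats2) and 7 fell, with Ankrd1, a muscle ankyrin repeat gene, at -0.75 on the log2 scale (adjusted p = 0.176). Of 26 cell cycle genes 5 rose (Tyms, Mcm6, Top2a, Mcm5 and Ccne1) and Bub1 and E2f1 fell (adjusted p = 0.132). Tyms, thymidylate synthase, rose by 0.54. The call of Bub1, a spindle checkpoint kinase (-0.36), was lost in DESeq2 and without induced library 1 (-0.21). Of 16 p53 targets, 5 rose (Fas, Ccng1, Bbc3, Aen and Gtse1) and 6 fell (adjusted p = 0.641), with the death receptor gene Fas at 1.00 and the polo-like kinase gene Plk2 at -0.67. The counts of these 3 lists were the same adjusted over the list alone, as were those of the next 5. Of 15 Wnt and beta-catenin targets, Tcf7 (the induced gene itself, at 6.04), Ccnd1 and Sox9 rose and Myc, Znrf3, Lef1 and Rnf43 fell. The list had a median of -0.02 and a mean of 0.29, which Tcf7 raised. Camera pointed down (adjusted p = 0.951), but up without induced library 2 (median 0.05). Rnf43, a ubiquitin ligase that restrains Wnt receptors (-1.17), was lost in DESeq2, limma-voom, after a correction against expression level (-0.91) and without normal library 1 (-0.41) or induced library 1 (-1.17). Of 11 early progenitor factors Mycn rose (0.87) and Cd34, a progenitor surface protein also made by fibroblasts (-1.09, SE 0.04), and Meis1 fell, with a median of 0.02, a mean of -0.02 and a test pointing down (adjusted p = 0.951), but up without normal library 2 (median 0.07). Mycn was lost in DESeq2 and without normal library 1 (0.76) or induced library 1 (0.81). Of 7 NK and innate lymphoid genes, Il2rb (2.39) and Zbtb16 (1.62) rose and Il1rl1, Id2 and Rora fell (adjusted p = 0.257). The call of Zbtb16 was lost without normal library 1 (1.53), normal library 2 (1.73) or induced library 2 (1.24). Of 7 myeloid genes, Cebpb (0.68), Cd14 (1.24), the lipopolysaccharide co-receptor, and Cd68 rose (adjusted p = 0.173), and of 3 B lineage genes, too few for the list test, Cd74 (1.66) and Ebf1 (0.20) rose. With 5 members tested, the B lineage list passed upward without normal library 1 (median 0.79, adjusted p = 0.0316) and induced library 1 (0.81, adjusted p = 0.0106), but not without normal library 2 (0.33, adjusted p = 0.0541).

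Genes of chromatin looping moved little in 3T3. Of 15 members of the cohesin and CTCF list, Yy1 (-0.22, SE 0.04), Ldb1 (-0.20, SE 0.04), Stag2, Rad21 (-0.14, SE 0.04) and Nipbl fell and 0 rose (7 fell adjusted over the list alone), with a median of -0.09 and an adjusted p of 0.176. Rad21, a cohesin subunit, was lost without normal library 1 (-0.12) or normal library 2 (-0.15), and after corrections against expression level (-0.08) or GC content (-0.07). Ctcf, the insulator-binding factor, did not pass, with 84.7 ± 1.04 CPM in normal and 88.4 ± 1.95 CPM in induced cells (log2 fold change 0.06, SE 0.05, adjusted p = 0.364). Mitochondrial transcripts and T cell receptor constant genes had 0 tested members in 3T3, where all 37 mitochondrial genes of the table stood at 0. This comparison is limited by 2 libraries per group. Doxycycline is named in the headers of the induced libraries alone. An effect of the drug therefore cannot be told apart from one of TCF-1 in any gene or list here. The strand setting of the counting is not given, so genes that overlap an antisense or neighbouring gene are uncertain. Among those named here these are Tes, Pappa2, Plxna4, Notch1, Cd34, Cd74, Cebpb, Col4a1, Aldh1l2, Ankrd37, Idi1, Ldb1, Gata3, Ctcf and Lef1. Members of the Oas and Gbp families are also uncertain, since related copies can share reads.

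**Figure D3:**
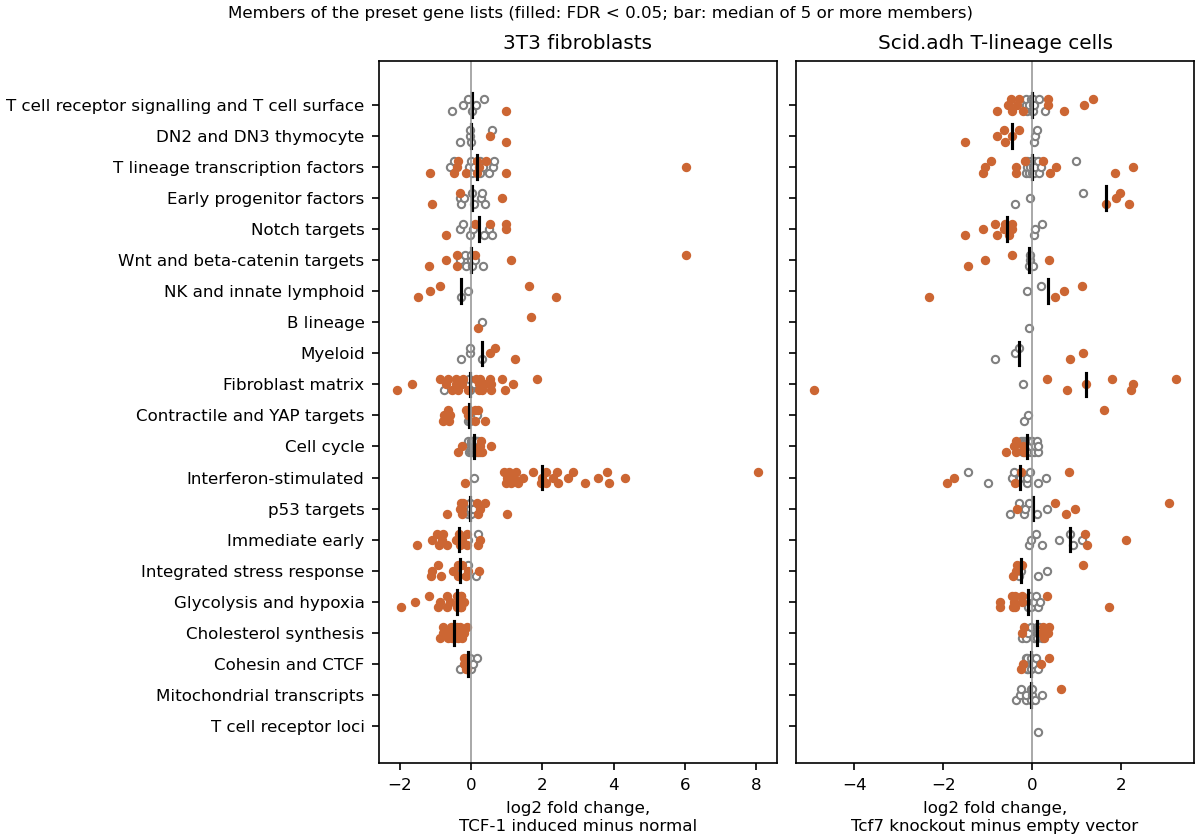
Log2 fold change of each tested member of the 21 preset lists in 3T3 (induced minus normal, left) and Scid.adh (knockout minus empty vector, right). Each point is a gene, filled at an adjusted p under 0.05, and each bar is the median of a list with at least 5 tested members; in 3T3 the interferon list lies highest (median 1.97), and in Scid.adh the Notch list lies below 0 (median -0.58).

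The comparison of knockout with empty-vector Scid.adh cells asks which transcripts depend on TCF-1 in a T-lineage cell that has it. Lag3, an inhibitory receptor of T cells (chromosome 6, 124904361 to 124911705), rose from 0.264 ± 0.231 to 67.6 ± 3.96 CPM (mean ± SD, n = 2), a log2 fold change of 7.95 (SE 0.26). Also rising were Sorbs2, a cytoskeletal adaptor (5.32, SE 0.39), Ndrg1, a stress- and hypoxia-induced gene (4.32, SE 0.19; 1.87 ± 0.0767 to 37.4 ± 0.122 CPM), the glycosyltransferase gene Galnt6 (4.26, SE 0.38), the scaffold gene Whrn (3.54, SE 0.25) and the tetraspanin gene Tspan15 (3.45, SE 0.30). The lowest log2 fold changes were those of the non-coding RNA gene Lncenc1 (-6.42, SE 0.19), Ifitm2, an interferon-induced membrane protein (-6.10, SE 0.32; 29.8 ± 0.858 to 0.417 ± 0.418 CPM), and the cytochrome gene Cyp2c55 (-5.51, SE 0.26). Next came Pdgfrb, a growth factor receptor of mesenchymal cells (-4.90, SE 0.13; 122 ± 3.85 to 4.09 ± 0.410 CPM), Fam3c (-4.71, SE 0.32) and Taf9b (-4.58, SE 0.33). The largest adjusted p of these 12 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 6.2e-06. In all, 1861 of 11941 tested genes rose and 1899 fell. This split depended on the scaling and the libraries: upper-quartile factors gave 2455 and 1215, DESeq2 641 and 1339, a test against 1.5-fold 565 and 159, the fit without empty-vector library 1 gave 1059 and 1162 and that without empty-vector library 2 gave 1180 and 1198. Camera called 5 of 18 lists, 0 of 18 with an estimated correlation (under the limit given for 3T3), and fry called 9 of 18. Fry called 6 with DESeq2 size factors, 1 under the replicate block, 1 without empty-vector library 1, 0 without empty-vector library 2, 0 without knockout library 1 and 8 without knockout library 2.

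Notch targets fell in the knockout libraries. Of 12 measured, 9 fell and Igf1r, Hes1 and Notch3 did not pass, with the same counts adjusted over the list alone and a median of -0.58. Notch1 dropped from 1590 ± 61.0 to 736 ± 80.6 CPM (log2 fold change -1.11, SE 0.07) and Nrarp, a feedback inhibitor of Notch signalling, from 83.3 ± 3.47 to 29.1 ± 1.28 CPM (-1.52, SE 0.10). The list's adjusted p from camera was 0.00105 (adjusted p = 0.447 with an estimated correlation, the highest of 8 alternatives, whose lowest was 9.16e-04). Of 9 DN2 and DN3 genes, which share members with the Notch list, 6 fell and Arpp21, Hes1 and Notch3 did not pass, again the same adjusted over the list alone, with a median of -0.47. Dtx1, a Notch-induced ubiquitin ligase (-0.79, SE 0.06), Ptcra, the pre-T cell receptor alpha chain (-0.64, SE 0.09), and Il2ra, the interleukin 2 receptor alpha chain (-0.62, SE 0.06; 1261 ± 3.76 to 821 ± 33.7 CPM), were among them. Its adjusted p was 0.0265 (adjusted p = 0.447 with an estimated correlation, against a lowest of 0.0169), and the call was lost without knockout library 1 (median -0.37). Among 10000 random gene sets matched on expression level, 0% had a median below that of the Notch list and 0.02% below that of the DN2 and DN3 list.

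T cell genes went both ways. Of 24 tested genes of T cell receptor signalling and the T cell surface, 5 rose (Trat1, Cd28, Themis, Cd96 and Zap70) and 7 fell, the same adjusted over the list alone. Trat1, an adaptor of the receptor complex, rose from 19.3 ± 0.235 to 49.5 ± 1.70 CPM (log2 fold change 1.36, SE 0.11), Cd28, the co-stimulatory receptor, by 0.71 (SE 0.09) and Cd96 by 1.16 (SE 0.29), while Cd2, an adhesion receptor, fell by 0.79 on the log2 scale. Cd96 was lost in DESeq2 and without knockout library 2 (0.86). It was also lost after a correction against expression level (0.78). The median of that list was -0.02 and its mean 0.03, with a test pointing down (adjusted p = 0.657). Of 26 T lineage transcription factors, 5 rose (Runx3, Sox13, Myb, Gfi1 and Bcl6) and 6 fell, the targeted gene Tcf7 itself among them, the same adjusted over the list alone. The median was 0.00 and the mean 0.07, with a test pointing down (adjusted p = 0.757), but up without knockout library 1 (median 0.09). Runx3, a factor of CD8 T cells, rose from 1.497 ± 0.305 to 7.19 ± 1.92 CPM (2.25, SE 0.34) and Sox13, a factor of gamma-delta T cells, by 1.85 (SE 0.38). Nfatc2, a calcium-dependent factor (-0.92, SE 0.08), and Runx1 (-0.38, SE 0.08) fell. Myb rose by 0.24 (SE 0.06), but not without empty-vector library 1 (0.21) or library 2 (0.24). Gata3 (325 ± 7.18 and 354 ± 9.21 CPM; log2 fold change 0.12, adjusted p = 0.144) and Bcl11b, a T cell commitment factor (677 ± 2.22 and 683 ± 54.5 CPM; log2 fold change 0.01, adjusted p = 0.913), did not pass. Gata3 passed with upper-quartile factors (0.20), without knockout library 1 (0.14), among genes of at least 5 CPM (0.18) and after corrections against expression level (0.25) or GC content (0.18). Bcl11b turned downward in DESeq2 (-0.03), without any filter (-0.04), in the fit of all 8 libraries (-0.01) and without knockout library 2 (-0.07) or empty-vector library 1 (-0.0033), and it passed upward after the correction against level (0.18). Nfatc2, Runx1, Myb, Gata3 and Bcl11b here, and Rad21 and Ctcf below, were added to the named genes after their values were seen. Of the T cell receptor constant genes only Trbc2 was tested, at 22.6 ± 3.69 and 24.7 ± 0.0845 CPM, and it did not pass (log2 fold change 0.13, adjusted p = 0.526; -0.04 without empty-vector library 2).

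Genes with few reads rose in the knockout libraries as a class, a measured feature of these libraries that several lists move with. With the tested genes in 10 classes of mean CPM, the median log2 fold change in the lowest class was 1.03, where 482 genes rose and 34 fell, and in the highest class -0.13. The knockout libraries had reads in 20406 and 20463 genes and the empty-vector libraries in 18084 and 18041, at lower totals in the knockout. The knockout libraries stood apart in other ways. They differed more from each other (chi-square per degree of freedom 6.89 over genes with at least 20 reads in the 2 libraries together) than the empty-vector libraries did (1.97). The gene model Gm26917 took 1.70% and 2.66% of their counts, compared with 3.51% and 3.52%, and the 10 highest genes took 4.91% and 5.90%, compared with 7.05% and 7.12%. After a correction of the values against expression level, 1395 genes rose and 1431 fell. Fibroblast matrix genes, mostly low here, rose with this trend: 7 of 9 tested rose, Pdgfrb fell and Col6a1 did not pass, the same adjusted over the list alone, with a median of 1.20. Loxl1, a matrix cross-linking enzyme, had 3 counts in the empty-vector and 26 in the knockout libraries, a ratio of 10.99 (95% counting interval 3.37 to 56.7), and its call was lost in DESeq2 and without empty-vector library 2 (log2 fold change 2.31). The list's adjusted p was 0.0330 (adjusted p = 0.447 with an estimated correlation, against a lowest of 0.0169). It was lost with a minimum mean of 1 CPM and without knockout library 1 (median 1.05, compared with 1.08 on the same scale with all libraries), and its median ranked at 94.0% among random sets matched on level. Of 11 immediate early genes Klf2, Junb and Egr1 rose and 0 fell, the same adjusted over the list alone, with a median of 0.85 and an adjusted p of 0.0330 (adjusted p = 0.447 with an estimated correlation, against a lowest of 0.0169). Klf2, a factor of quiescent T cells, went from 0.519 ± 0.0213 to 2.28 ± 0.209 CPM and was lost in DESeq2, as was Egr1 (log2 fold change 1.24), which was also lost without any filter and without each library in turn (0.94 to 1.59). The list's call was lost without knockout library 1 (median 0.89, compared with 0.74 on that scale with all libraries), and its median ranked at 87.5% among matched sets. Of 7 early progenitor factors, Flt3, Bcl11a (2.16, SE 0.55), Tal1 and Gata2 (1.97, SE 0.54) rose and 0 fell (5 up adjusted over the list alone). The list did not pass camera (median 1.64, adjusted p = 0.0652). It passed under the replicate block (adjusted p = 0.0421) and without empty-vector library 1 (median 1.58), empty-vector library 2 (1.26) or knockout library 2 (1.65), compared with 1.48 on that scale with all libraries. The median ranked at 96.9% among matched sets. DESeq2 called neither Bcl11a nor Gata2. The former was also lost without empty-vector library 1 (2.66), empty-vector library 2 (1.79) or knockout library 1 (2.01), the latter without knockout library 1 (0.90). After the correction against level the calls of Bcl11a (0.93), Gata2 (0.94), Klf2 (1.09) and Egr1 (0.54) were lost.

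**Figure D4:**
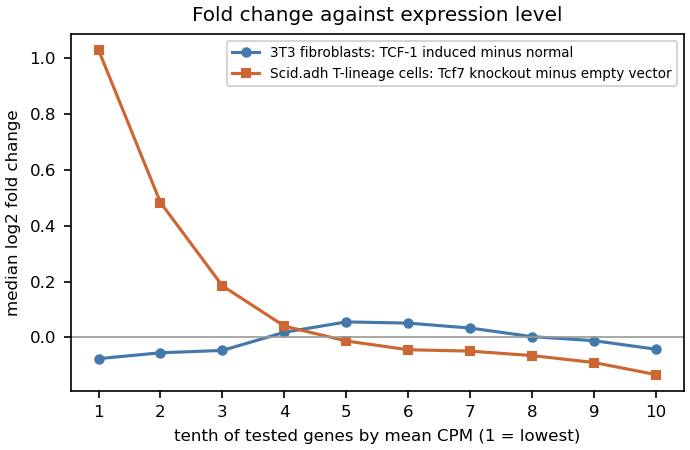
Median log2 fold change in each of 10 equal classes of the tested genes by mean CPM, from the lowest (1) to the highest (10), in 3T3 (circles, induced minus normal) and Scid.adh (squares, knockout minus empty vector). The Scid.adh line runs from 1.03 in the lowest class to -0.13 in the highest, while that of 3T3 stays between -0.08 and 0.06.

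Of 26 cell cycle genes, 6 fell in the knockout and 0 rose, the same adjusted over the list alone, with a median of -0.13 that lay near that of sets matched on level (-0.11). Tyms fell by 0.60 on the log2 scale (107 ± 5.81 to 70.6 ± 8.09 CPM) and Cdc20, an activator of the anaphase-promoting complex, by 0.40. The list's adjusted p was 0.0330 (adjusted p = 0.447 with an estimated correlation, against a lowest of 0.0218). It was lost with a minimum mean of 1 CPM and without knockout library 2 (median -0.09), and its median ranked at 31.2% among sets matched on level. The interferon list did not pass (15 tested, median -0.28, adjusted p = 0.152), although its median ranked at 0.23% among sets matched on level: 4 fell, with Gbp3 (-1.93, SE 0.42) and Zbp1 (-1.77, SE 0.43) among them, and Mx1 rose, the same adjusted over the list alone, and Zbp1 was lost in DESeq2. Of 19 glycolysis and hypoxia genes, Bnip3, a hypoxia-induced mitophagy gene (1.72, SE 0.21), and Pgk1 rose and 9 fell, among them the phosphofructokinase gene Pfkp (-0.72, SE 0.11), with 3 and 9 adjusted over the list alone (adjusted p = 0.102). Of 18 cholesterol genes, 5 rose, with Hmgcs1 and Cyp51 among them, and 2 fell, the same adjusted over the list alone (median 0.10, adjusted p = 0.463, at 99.89% among matched sets). Cyp51 rose by 0.37, but not without empty-vector library 2 (0.31), and Hmgcs1, the first committed enzyme of the pathway, by 0.36. Of 9 integrated stress response genes, Slc7a11, the cystine transporter (1.14, SE 0.13), rose and Psat1, a serine synthesis enzyme (-0.43, SE 0.06), Atf4, Slc7a5 and Phgdh fell, with 2 up and 4 down adjusted over the list alone (adjusted p = 0.383). Of 12 p53 targets, Btg2 (0.96, SE 0.08), Fas (3.08, SE 0.37), Zmat3 and Trp53inp1 rose and Aen fell, the same adjusted over the list alone (adjusted p = 0.657).

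Beside fibroblast matrix, lists of other lineages gave no camera call in Scid.adh when all 4 libraries were used. Of 6 NK and innate lymphoid genes, Gzma, Eomes, an NK and memory T cell factor (1.12, SE 0.18), and Rora rose and Fcer1g, a signalling chain of Fc receptors (-2.33, SE 0.31), fell (4 up and 1 down adjusted over the list alone; adjusted p = 0.553, median at 98.95% among matched sets). Of 5 myeloid genes, Cebpa, a myeloid master regulator (1.14, SE 0.17), and Itgam (0.85, SE 0.25) rose, the same adjusted over the list alone, with a median of -0.30, a mean of 0.11 and a test pointing up (adjusted p = 0.838), but down without knockout library 1 (median -0.33) or empty-vector library 2 (-0.20). Itgam was lost in DESeq2, after a correction against expression level (0.68) and without empty-vector library 2 (0.59). The B lineage list had 1 tested gene, Pou2af1, which did not pass (-0.08), and of 3 contractile and YAP targets Ccn1 rose (1.61, SE 0.38), a call lost in DESeq2, after the correction against level (0.85) and without empty-vector library 2 (1.499). With 5 members tested, that list passed upward without empty-vector library 1 (median 1.51, adjusted p = 0.0366), and it did not pass with any of the other 3 libraries left out. Of 8 Wnt and beta-catenin targets, Axin2 rose and Tcf7 (the targeted gene itself), Myc and Bambi (-1.45, SE 0.37) fell. The counts were the same adjusted over the list alone (adjusted p = 0.122), and DESeq2 did not call Bambi. Of 12 mitochondrial transcripts mt-Nd3 rose (0.65, SE 0.17), the same adjusted over the list alone, a call lost in DESeq2, after a correction against GC content (0.39) and without empty-vector library 2 (0.50). The list did not pass (median -0.11 on the scale of the test, adjusted p = 0.657), and it passed upward without knockout library 1 (median 0.35) and downward without knockout library 2 (-0.60). The share of counts on mitochondrial genes was 0.524% and 0.976% in the knockout libraries and 0.716% and 0.719% in the empty-vector libraries. Of 15 cohesin and CTCF genes, Esco1 (0.37, SE 0.09) and Stag2 rose and Smc1a (-0.26, SE 0.06) and Rad21 (-0.20, SE 0.06) fell, with 1 up and 2 down adjusted over the list alone (adjusted p = 0.623). Esco1 was lost in DESeq2, after the correction against GC content (0.24) and without empty-vector library 2 (0.34). Smc1a was lost without empty-vector library 1 (-0.25) or library 2 (-0.29) and after the correction against level (-0.09). Rad21 was lost with upper-quartile factors (-0.12), among genes of at least 5 CPM (-0.15), after the correction against level (-0.03) and without the same libraries (-0.20 and -0.23). Ctcf stood at 312 ± 2.01 and 289 ± 15.6 CPM and did not pass (log2 fold change -0.11, adjusted p = 0.211), but passed without knockout library 2 (-0.16) and turned upward after the correction against level (0.02). The strand setting is not given here either, so Sorbs2, Galnt6, Tspan15, Cyp2c55, Nrarp, Bcl11a, Eomes, Cebpa, Itgam, Cdc20, Bnip3, Pfkp, Cyp51, Hmgcs1, Runx1, Myb, Gata3, Ndrg1, Ifitm2, Notch1, Ctcf and Lef1, which overlap another gene's exons, are uncertain, and Ifitm2 and Cyp2c55 also have close paralogs.

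A further question is whether genes that responded to gaining TCF-1 in fibroblasts also responded to losing it in T-lineage cells. Among 11038 genes tested in both lines, 527 rose with induction and fell in the knockout, where independent lists would share 391 (Fisher's exact test, adjusted p over 4 classes 4.77e-16), and 338 fell with induction and rose in the knockout, against 310 (adjusted p = 0.0736). In the classes that moved against TCF-1, 287 genes rose in both comparisons against 346 (adjusted p = 0.000161) and 350 fell in both against 349 (adjusted p = 0.974). Genes are not independent replicates, so these p-values describe the lists. Calls also followed expression level in each line, which independent lists do not allow for. From the lowest to the highest of 10 level classes, rises in 3T3 went from 83 to 501 genes and falls from 112 to 714. In Scid.adh rises went from 482 to 72 genes and falls from 34 to 453. No expectation matched on level was computed, so level may account for part of these excesses and deficits. In sum 865 genes moved with TCF-1 in both lines and 637 against it, compared with 700 and 695 for independent lists. DESeq2 calls gave 350 and 256, compared with 214 and 215, and calls of at least 2-fold 27 and 22, compared with 9.80 and 12.8. The genes moving against TCF-1 thus went from 0.916 times the number of independent lists to 1.19 and 1.72 times, while genes of at least 5 CPM in both lines stayed at 0.929 times (489 against 527, and 701 against 546 with TCF-1). The classes were not equally firm: the class that fell with induction and rose in the knockout passed with DESeq2 calls (101 against 62.5, adjusted p = 1.53e-06) and among genes of at least 5 CPM (222 against 161, adjusted p = 7.99e-08), but not at 2-fold (12 against 7.66, adjusted p = 0.168). The class that rose in both was lost with DESeq2 calls (adjusted p = 0.945) and among genes of at least 5 CPM (adjusted p = 0.0774), and at 2-fold it did not pass, at 19 against 11.3 (adjusted p = 0.0547). The class that fell in both passed with DESeq2 calls (194 against 153, adjusted p = 0.000392), but not at 2-fold (adjusted p = 0.177) or among genes of at least 5 CPM (adjusted p = 0.279). The class that rose with induction and fell in the knockout passed in all 3 of these settings. With the Scid.adh change turned to empty vector minus knockout, the log2 fold changes of the 2 comparisons had a Pearson correlation of 0.0287 across these genes. Ndrg1 fell in induced fibroblasts (268 ± 2.51 to 108 ± 3.99 CPM) and rose in the knockout. Ifi202b, a sensor-like gene of the interferon-induced HIN-200 family, rose from 118 ± 1.73 to 168 ± 13.9 CPM in 3T3 and fell from 48.5 ± 5.58 to 3.43 ± 0.823 CPM in Scid.adh, and Ifitm2 went from 96.3 ± 2.54 to 187 ± 8.58 CPM in 3T3 and fell in Scid.adh as given above. Against TCF-1 went Clic4, a chloride channel family member that rose in both lines (113 ± 0.771 to 162 ± 5.88 and 20.1 ± 3.46 to 136 ± 5.65 CPM), and Ccn4, a secreted Wnt-induced protein that also rose in both (75.1 ± 0.427 to 100 ± 4.85 and 40.0 ± 0.264 to 102 ± 7.68 CPM). Svil, a gene of the actin cytoskeleton, fell in both (263 ± 0.501 to 171 ± 6.53 and 170 ± 6.63 to 61.4 ± 6.76 CPM), as did Pdgfrb (392 ± 3.41 to 336 ± 8.82 CPM in 3T3).

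The contrast of more with less TCF-1 differed between the lines for many genes, with doxycycline in 3T3 and preparation in Scid.adh not separated from TCF-1. In a joint fit of all 8 libraries over 15854 genes, the contrast (induced minus normal in 3T3, set against empty vector minus knockout in Scid.adh) was higher in 3T3 for 2294 genes and lower for 2274, and with DESeq2 size factors for 2054 and 2736. Tcf7 differed by 4.94 (SE 0.08, adjusted p = 3.32e-31) and Lef1 by -0.49 (SE 0.13, adjusted p = 0.00521). Among the gene lists, the contrast was higher in 3T3 for interferon-stimulated genes (median difference 1.31, adjusted p = 3.22e-07), fibroblast matrix genes (0.91, adjusted p = 0.000606) and early progenitor factors (1.24, adjusted p = 0.0366). It was lower for glycolysis (-0.69, adjusted p = 6.78e-09), cholesterol synthesis (-0.43, adjusted p = 7.88e-07), the integrated stress response (-0.65, adjusted p = 0.00251) and cohesin and CTCF (-0.17, adjusted p = 0.0366). With an estimated correlation the interferon, glycolysis and cholesterol lists each gave an adjusted p of 0.0351, and the other 4 did not pass: adjusted p = 0.0568 with an estimated correlation for fibroblast matrix, 0.373 for early progenitor factors, 0.0816 for the integrated stress response and 0.592 for cohesin and CTCF. Counts of the 2 lines were made on different gene tables, and low-expressed genes rose in the knockout libraries (median 1.03 in the lowest of 10 classes). Whether that trend moves the differences of the lists was not tested. For fibroblast matrix and early progenitor factors the difference lay in Scid.adh (median empty vector minus knockout -1.03 and -1.09). In 3T3 their medians in the joint fit were -0.0028 and 0.014. The joint fit held 28 and 15 members of these lists, while 9 and 7 were tested in the fit of Scid.adh alone.

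Since the series is about genome folding, changes were also set against gene order. In 3T3, 31.0% of called genes had as their next tested neighbour a gene called in the same direction, compared with 18.4% on average over 10000 random placements of the calls (95% range 17.5% to 19.3%), and in Scid.adh 20.8% compared with 15.8% (14.7% to 16.8%). With calls of at least 2-fold the ratio of observed to random share was 7.41 in 3T3 and 1.62 in Scid.adh. The one-sided permutation p was 1e-04 in each line, the smallest value these placements can give. The Serpina3 cluster on chromosome 12 belonged to a run of 9 neighbours that rose in 3T3 (104189517 to 104751952, median log2 fold change 2.25), and the HIN-200 cluster on chromosome 1 to a run of 8 that rose in 3T3 (173468485 to 173982744, median 0.72) and a run of 6 that fell in Scid.adh (173747293 to 175625635, median -3.38); these clusters were chosen after their values were seen. Left without neighbours that overlap or lie within 5 kb, the ratio of observed to random share was 1.52 in 3T3 and 1.35 in Scid.adh. Whole chromosomes differed by small amounts. In 3T3, 12 of 20 chromosomes had a median outside the central 95% of random gene sets, from -0.06 (chromosome 3) to 0.06 (chromosome 17). In Scid.adh 6 of 20 did, from -0.05 (chromosome 15) to 0.09 (chromosome 13). With genes drawn independently, 1 of 20 is expected. These sets do not allow for neighbours that move together or for GC content. In 3T3 the median went from -0.10 in the lowest of 10 GC classes to 0.09 in the highest.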

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

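The values in this paragraph were picked out by a passed test of the difference between lines in the fit of all 8 libraries, made here for Tcf7, Lef1, the genes named for shared calls and the lists. For Tcf7 the contrast of more with less TCF-1 differed by 4.94, a difference of fold changes from unlike starting levels (14.55 to 958.7 CPM in 3T3, 1322 to 635.4 CPM in the Scid.adh knockout), and for Lef1 by -0.49. Genes whose contrast in 3T3 was higher were Ndrg1 (2.97), Clic4 (3.24) and Ccn4 (1.72), and genes whose contrast was lower were Ifi202b (-3.35), Ifitm2 (-5.20), Svil (-2.13) and Pdgfrb (-5.17). Of these, Ndrg1, Ifi202b and Ifitm2 moved with TCF-1 in both lines by different amounts, while Clic4 and Ccn4 rose, and Svil and Pdgfrb fell, in both comparisons. Lists with a passed difference were early progenitor factors (median difference 1.24), fibroblast matrix (0.91), interferon-stimulated genes (1.31), the integrated stress response (-0.65), glycolysis and hypoxia (-0.69), cholesterol synthesis (-0.43) and cohesin and CTCF (-0.17). With an estimated correlation 4 of these did not pass: early progenitor factors (adjusted p = 0.373), fibroblast matrix (0.0568), the integrated stress response (0.0816) and cohesin and CTCF (0.592). Of the 94 other named genes in that fit, 28 were higher and 22 lower in 3T3, among them Fas (4.04), Gata3 (0.71) and Rad21 (-0.38), which were named in both lines.

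For the rise of interferon-stimulated genes in induced fibroblasts, the GC test was written before its result was seen, and the leukocyte and doxycycline tests after. Blood cells in the induced cultures would raise leukocyte markers, but the summed CPM of markers was 1.13 times the normal level over markers below 50 CPM. That limit was set after the sum over all 14 markers had given 0.758, a value set mostly by Arhgdib. With the trend of fold changes with GC content removed (Spearman correlation across genes 0.188), all 25 raised members stayed raised. Doxycycline acting without TCF-1 cannot be told apart from TCF-1 here, because 0 induced libraries were made without it.

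For the rise of low-expressed genes in the knockout libraries, all 3 tests were chosen after the result was seen. Silent receptor families rose from 0.0105 and 0.0106 to 0.0208 and 0.0216 CPM per kb of exon. This excess is 7.20% of the median excess per kb in the lowest class of tested genes. On that measure an even background of genomic DNA is small. Those lowest genes were also selected by the filter, which favours genes that are high in either group. The share may therefore be too low, and the test does not exclude such a background. At lower totals, the knockout libraries already had reads in 20406 and 20463 genes, against 18084 and 18041 with the empty vector. The different depth therefore does not account for the higher number of genes detected. With all libraries thinned to 7740198 reads, the lowest knockout library had 2878 more genes detected than the highest empty-vector library. The unthinned values had fixed the direction of that outcome, so it is no separate check. A difference between library preparations cannot be told apart from an effect of the knockout, because the labels name 0 preparations shared by the groups.

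For neighbours called in the same direction, the tests of shared reads were chosen before the result was seen and those of level, GC content and gene span after it, with their classes redrawn once after a version without span. With calls placed within such classes, the highest of 10000 placements reached 20.6% in 3T3 and 18.7% in Scid.adh, below the observed 31.0% and 20.8%. Without overlapping, close or like-named neighbours the observed share was still 1.47 times the random share in 3T3 and 1.31 times in Scid.adh. Taken one at a time, neither the shared properties nor overlapping, close or like-named neighbours accounted for all of the excess in either line. They were not tested together. Neighbours that both lie within a longer gene were not left out, so shared reads are not ruled out.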

How the results depend on the processing

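Among main counts set beside each alternative, 113 kept within 1.5-fold and 21 moved by more. For single genes and lists, 1979 kept their call and direction, 132 lost a call, 14 gained a call and 22 changed direction. The cause of a move was not tested unless given. A test against 1.5-fold calls fewer genes by construction: 480 up and 437 down in 3T3 and 565 and 159 in Scid.adh, with 43 named gene calls lost. DESeq2 called 1803 and 1845 genes in 3T3 and 641 up in Scid.adh, and 17 named gene calls were lost. Upper-quartile factors left 1215 genes down in Scid.adh, and a minimum of 5 CPM, with fewer genes tested, 1247. With 1 Scid.adh library left out, and so fewer samples, 1059 to 1911 genes were up and 1162 to 2321 down, and 3 to 7 lists were called. An estimated correlation left 0 lists called in each line, and a minimum of 1 CPM left 3 in Scid.adh. DESeq2 calls gave 350 shared genes with TCF-1 and 256 against, and calls of at least 2-fold, fewer by construction, 27 and 22. Most turned directions were of values near 0. Under the replicate block the test turned for T cell receptor signalling (median 0.0193), early progenitor factors (0.0405) and fibroblast matrix (-0.0488) in 3T3 and for myeloid genes (-0.29) in Scid.adh. Left-out libraries gave medians in 3T3 from -0.0827 to 0.0721 for T cell receptor signalling, -0.17 to 0.0691 for early progenitor factors, -0.21 to 0.0536 for Wnt targets and -0.0623 to -0.0263 for fibroblast matrix. In Scid.adh they gave -0.0688 to 0.0868 for T lineage factors, -0.33 to 0.39 for myeloid genes and -0.60 to 0.35 for mitochondrial transcripts. Bcl11b in Scid.adh turned in DESeq2 (-0.0314), without a filter (-0.0446) and in the fit of 8 libraries (-0.0120), and ranged from -0.0688 to 0.0807 with a library left out, and Trbc2 from -0.0376 to 0.30. Lef1 turned with upper-quartile factors (0.0256), a minimum of 5 CPM (0.0023) and a correction against expression level (0.0946), which also turned Ctcf (0.0175). The last 2 settings, the correction against GC content and 2 settings of the neighbour test were added after the data were seen. Early progenitor factors in Scid.adh passed under the replicate block (adjusted p = 0.0421, limma camera), which changed no other camera call of a list and no call of a named gene, but left 8 fry calls in 3T3 and 1 in Scid.adh (13 and 9 in the main run), while 7210 genes were called in 3T3 and 4038 in Scid.adh. Replicate numbers did not behave as pairs, with a correlation of 0.0124 in 3T3 and 0.00147 in Scid.adh between residuals of libraries with the same number. The tests were less able to find small changes: 34.0% of the smallest simulated changes were found in 3T3 and 22.4% in Scid.adh. The alternative for values that are not counts does not apply.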

Other observations

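Families chosen after the data were seen held further raised genes in induced fibroblasts. Here and below, related copies within a family, such as the Serpina3 and HIN-200 genes, can share reads. Members are therefore not separate observations. Of 7 tested Serpina3 genes, which encode secreted protease inhibitors of the acute phase, all 7 rose (median log2 fold change 2.25), with Serpina3n going from 46.9 to 254.5 CPM. Complement genes rose in 6 of 9 cases (4 of 8 in DESeq2), among them C3 (1597 to 4248 CPM), C4b (2.45, SE 0.09) and Cfb (2.74, SE 0.13), and 7 of 14 chemokine genes rose and 2 (Ccl25 and Ccl5) fell, with Cxcl5 at 1.75 and Ccl11 at 4.06 (5 up and 0 down in DESeq2, and 8 up and 0 down without induced library 1, median 0.28). Guanylate-binding and immunity-related GTPases, which act against microbes inside cells, rose in 13 of 14 cases (median 1.66). Class I H2 genes, which present peptides to T cells, rose in 8 of 16 (5 of 15 in DESeq2; median 0.54, with H2-K1 from 26.6 to 53.3 CPM).

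In Scid.adh knockout cells the tested HIN-200 genes and some GTPases and class I H2 genes fell, although the preset interferon list did not pass there. Serpina3 and complement genes had 0 tested members, and of 3 chemokines 1 fell and 0 rose (median 0.05). All 5 tested HIN-200 genes fell (median -3.82), with Ifi203 going from 76.5 to 17.6 CPM and Mndal from 16.2 to 2.10 CPM, while 8 of 9 rose in induced fibroblasts (median 0.68). GTPases fell in 5 of 7 cases (median -1.09), but in 2 with DESeq2 or against 1.5-fold, in 2 without empty-vector library 2 (median -0.83) and in 3 without knockout library 1 (-0.96, with 1 up). Class I H2 genes fell in 4 of 8 (H2-D1, H2-K1, H2-T22 and H2-T3; median -0.68), with H2-T3 going from 147 to 74.0 CPM. In the knockout libraries 9 of 17 Hox genes also rose (median 1.14, at 98.3% among sets matched on level), 13 of 23 collagens (0.78, at 95.03%) and 74 of 262 Zfp zinc finger genes against 11 that fell (0.23, at 100%). Of the tested genes, 4 Hox genes and 6 collagens reach a mean of 5 CPM. These counts depend on the setting. DESeq2 called 5 Hox genes, 3 collagens and 29 Zfp genes up, and a test against 1.5-fold 5, 4 and 6. Without empty-vector library 1 the counts were 6, 8 and 53, and without library 2 they were 7, 8 and 52. After a correction against expression level 6 Hox genes rose (median 0.36), 3 collagens rose and 1 fell (0.45), and 72 Zfp genes rose (0.20). On chromosome 12 the imprinted region from Begain to Rian (109032187 to 109661716) held a run of 9 genes that fell in induced fibroblasts (median -0.84). A run of 5 genes from the same start (to 110583062), with Begain, Dlk1, Mirg, Dio3 and Ppp2r5c, rose in the knockout (2.12).

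A hypothesis is that TCF-1 raises a set of interferon-linked genes, such as the HIN-200 genes, in both cell types. It may instead be an answer to doxycycline in the fibroblasts, where 0 induced libraries lack the drug, while leukocytes, at 1.13 times the normal marker sum, are a poor account of it. In Scid.adh it may be a trait of the knockout cells unrelated to TCF-1. Induction without doxycycline, doxycycline without Tcf7, and an independent knockout with Tcf7 restored would test it.

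A hypothesis for the low-expressed genes is that loss of TCF-1 loosens the repression of silent genes, perhaps with some Hox and collagen genes among them. The libraries could also differ by preparation, as 0 preparations shared by the groups are named. A background of genomic DNA could add to the excess, at 7.20% by a measure that the filter may have lowered. New libraries of both groups made in the same batch, with added control RNA, would test it.

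A hypothesis for the runs of neighbours is that domains of chromatin respond as units. The share of same-direction neighbours was 1.47 times random in 3T3 and 1.31 times in Scid.adh without close or like-named genes. It could also come from shared enhancers, gene copies with unlike names or reads from a longer gene that holds both neighbours. Contact maps of the same cells, read at the HIN-200 and Begain to Rian regions, would test it.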
